A study of Mus musculus with 15 samples.

How the data were processed

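The data describe mouse testis at postnatal day 28, with 9 RNA-seq libraries (3 wild type, 3 heterozygous, 3 homozygous) and 6 small RNA libraries (3 heterozygous, 3 homozygous) from animals labelled B6D2F1. Groups were taken from the genotype labels. RNA-seq libraries were made from total RNA with a stranded kit after ribosomal depletion, per the labels' protocols. RNA for small RNA libraries was oxidised with periodate and β-eliminated, which removes RNAs without a 2′-O-methylated end, per the labels' protocols. The submitters' processing notes name cutadapt 1.18, FastQC 0.11.8, HISAT2 2.1.0, Bowtie2 2.2.5, SAMtools 1.9, Salmon 0.11.3, featureCounts 1.6.2, R 3.5.1 and DESeq2 1.20.0, with the mm10 and mm9 builds, without assigning roles.

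The authors deposited raw read counts per feature, not normalized. For RNA-seq, per the file headers, featureCounts counted properly paired fragments over whole gene bodies, introns included, for each strand setting in a separate file. The annotation held 49585 GENCODE genes and 466 piRNA precursors, 50051 features in all. Gene body counting means that unspliced RNA enters each value. A fragment in overlapping features of the same strand was not counted, and 248 genes overlap a precursor on the same strand. The kit reads the reverse strand, so those counts were used, and counts of the opposite strand (8.81 to 10.7% of the kit strand) served as a check. For small RNA, the deposited counts cover exons per gene on the sense strand, per the file headers, over 49585 genes and without piRNA precursors. Symbols were found for 49326 of the 49585 gene IDs in a reference of names. Biotypes and transcript sequences came from GENCODE for the mouse mm10 assembly. Coordinates are those of the files and of the mm10 build.

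Counts were analysed with edgeR 4.0.16, limma 3.58.1 and R 4.3.3, with the data.table package (version 1.17.8). Features with low counts were removed with filterByExpr by group, which left 20782 features in RNA-seq and 3581 in small RNA, and libraries were scaled by TMM. All 9 RNA-seq libraries entered 1 fit with group means, all 6 small RNA libraries another, and contrasts were tested with the edgeR quasi-likelihood test. A feature passed at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene is from this test unless DESeq2 1.42.0 is named. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM, counts relative to the scaled library size, as mean ± SD over 3 libraries. Intervals of a share are exact 95% intervals and cover counting error only. RNA-seq replicate numbers follow the order of the samples and pair nothing.

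The 23 gene lists and the rule for named genes were fixed before the data were examined. Named genes passed, changed at least 2-fold, had groups that did not overlap and reached 1 CPM in the higher group. The first 10 in each direction by adjusted p were taken, with at most 3 placeholder symbols, and up to 4 members of each list with the lowest p. The 13 genes Golga2, Gopc, Dpy19l2, Spaca1, Spata16, Zpbp, Pick1, Acr, Piwil1, Piwil2, Mov10l1, Mybl1 and Tdrd1 were fixed by name. In small RNA, a mean of 50 reads in the higher group was required. For the comparison with both controls, the homozygous libraries had to lie outside all 6 controls, a form of the rule set after the counts were seen. Lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. The lists cover acrosome formation and contents, Golgi matrix and golgin, piRNA pathway, spermatogonia, early meiotic prophase, pachytene and secondary spermatocytes, round spermatids, elongating spermatids, sperm flagellum and axoneme, manchette and head shaping, Sertoli cell, Leydig cell, peritubular myoid cell, macrophage and leukocyte, endothelial cell, red blood cell, epididymis, adipose tissue, interferon response, p53 and apoptosis, unfolded protein and heat shock, immediate early and mitochondrial genome. The planned rule for finding the locus from small RNA features of chromosome 18 was not run, because the small RNA counts used here hold no precursor features, and the annotated precursors in the RNA-seq counts took its place.

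Alternatives were DESeq2, RLE scaling, no scaling, no filter, a mean of at least 1 CPM, both strands summed, only the groups compared, a 2-fold limit, a covariate from the elongating spermatid list, a replicate block for small RNA, each library left out, and, chosen after the data were seen, a correction of gene length trends, small RNA without heterozygous libraries 2 and 3, and all alternatives for the opposite strand. The elongating spermatid list lay lower in both other groups than in wild type, so its covariate overlaps with the contrasts against wild type. A call lost with this covariate therefore does not show a cause. Overlaps of calls were set beside 20 simulations of unchanged groups with shared libraries. Antisense matches to the annotated transcripts of the locus were found with blastn 2.17.0 from Python 3.11.15 (at least 100 aligned nt and 80% identity, leaving out stretches that match more than 20 genes), and figures were drawn with matplotlib 3.10.9 and pandas 2.3.3. The tests were checked on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For homozygotes against wild type 83% and 98% were recovered among 20525 genes, with 11 false calls of 192. For homozygotes against heterozygotes these were 83% and 98%, with 13 of 194, and for both controls 88% and 100%, with 19 of 207. For small RNA they were 17% and 84% among 3413 genes, with 5 of 106, so 2-fold changes of small RNA were mostly not detectable.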

Results

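RNA was measured in testes of mice at postnatal day 28 that carried 2, 1 or 0 intact copies of a piRNA-producing locus on chromosome 18. Pachytene piRNAs are small RNAs made from long precursor transcripts in meiotic and haploid male germ cells and bound by PIWI proteins. Strand-specific total RNA-seq covered 3 wild-type, 3 heterozygous and 3 homozygous knockout testes. Small RNA sequencing covered 3 heterozygous and 3 homozygous testes, after a periodate treatment that favours RNAs with a methylated 3′ end, such as piRNAs. RNA-seq counts per library were 36936068, 26807554 and 21684791 in wild type, 41513634, 28639855 and 28876549 in heterozygotes, and 27933217, 29205925 and 25783931 in homozygotes. Small RNA counts over annotated genes were 1861402, 939641 and 1161653 in heterozygotes and 1446726, 1275655 and 1122409 in homozygotes. The labels describe the libraries as replicates without stating that each came from a separate animal, so p-values measure the spread between these libraries. All pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.12 to 50.7 in RNA-seq and 2.11 to 27.2 in small RNA.

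The targeted locus was examined first, because the series concerns mice without the chromosome 18 pachytene piRNAs. A pair of divergent piRNA precursors on chromosome 18 lost nearly all their RNA in the homozygotes. The minus-strand precursor 18_qE1_36451_1 (positions 67029446 to 67066460 in the mm10 build) stood at 273 ± 20.7 CPM (counts scaled to library size) in wild type, 163 ± 37.1 in heterozygotes and 0.156 ± 0.049 in homozygotes (SD, n = 3 each). Its counts were 9595, 7283 and 5609 in wild type, 8948, 3983 and 4422 in heterozygotes, and 4, 6 and 3 in homozygotes. The homozygous level was 0.0569% of wild type (95% exact interval of the count 0.0303 to 0.0973%, counting error only) and 0.0929% of the heterozygous level (0.0495 to 0.159%). The plus-strand precursor 18_qE1_1295_2 (67066587 to 67084379) stood at 39.8 ± 1.58, 22.2 ± 3.94 and 0.047 ± 0.054 CPM in the same groups (SD, n = 3 each). An isoform of it that covers 84.7% of its length was listed at 0 in all 9 libraries, because reads in overlapping features of one strand were not counted. Heterozygotes held 59.7% of the wild-type level of the minus-strand precursor (log2 fold change -0.74, SE 0.14, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.00496). For the plus-strand precursor they held 55.6% (-0.84, adjusted p = 0.0036). Each of the 9 RNA-seq libraries matched the genotype on its label, which was not checked in the small RNA libraries. Of 80 other piRNA precursors tested, 0 passed between homozygotes and heterozygotes in edgeR, with 0 at an unadjusted p under 0.05 and a median log2 fold change of -0.06. Against wild type, 12 were higher and 1 lower in homozygotes (median 0.18), and 19 higher and 1 lower in heterozygotes (median 0.20).

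**Figure D1:**
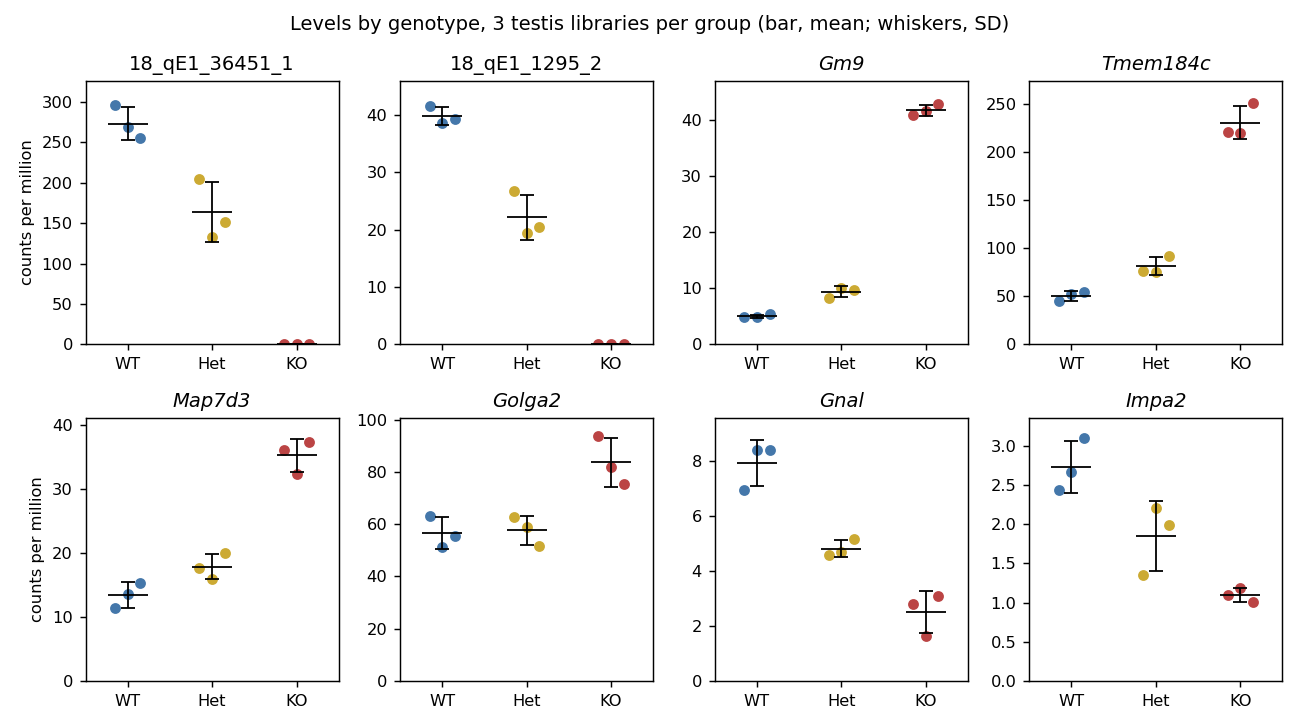
Normalised RNA-seq levels (CPM, linear axes from 0) of the 2 precursors, of Gm9, Tmem184c, Map7d3 and Golga2, and of the neighbouring genes Gnal and Impa2 in wild-type (WT), heterozygous (Het) and homozygous (KO) testes. Points are libraries, bars are means of 3 and whiskers are SDs; 18_qE1_36451_1 falls from 273 to 163 to 0.156, while Gm9 stands at 5.02, 9.35 and 41.8.

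Homozygotes were compared with heterozygotes to ask what the loss of the last intact copy changed. Few transcripts outside the locus differed, and those with the clearest change rose. Gm9, a protein-coding gene on chromosome X, rose from 9.35 ± 0.98 to 41.8 ± 0.98 CPM (SD, n = 3; log2 fold change 2.16, SE 0.10, edgeR adjusted p = 4.84e-07). Tmem184c, a gene on chromosome 8 for a transmembrane protein, rose from 81.0 ± 9.51 to 231 ± 17.2 CPM (1.51, SE 0.11, adjusted p = 5.39e-05). Both lay lowest in wild type, at 5.02 ± 0.26 and 50.5 ± 5.19 CPM. Both were also higher in heterozygotes than in wild type (log2 fold change 0.90, adjusted p = 6.15e-04 for Gm9, and 0.68, adjusted p = 0.003 for Tmem184c). Map7d3, a chromosome X gene of the microtubule-associated MAP7 family, rose from 17.8 ± 1.97 to 35.2 ± 2.56 (0.98, adjusted p = 0.0129). The long noncoding RNA Gm26561 fell from 24.6 ± 1.91 to 13.1 ± 0.71 (-0.91, adjusted p = 0.0129), and 20.8% of its length overlaps other genes of its strand. In wild type Gm26561 stood at 15.4 ± 1.95, near the homozygotes (adjusted p = 0.152 between them) and below the heterozygotes (adjusted p = 0.00345), so its level did not follow the number of intact copies. Map7d3 and Gm26561 fell short of the 2-fold limit for named genes and were chosen after their values were seen. In all, 3 of 20782 features were higher and 3 lower (2 of them the precursors), with 638 at an unadjusted p under 0.05 and 17 past the threshold by DESeq2. The groups did not overlap for 8.32% of features, against 10% by chance. Without heterozygous library 3 the test passed 18 features.

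Gm9 and Tmem184c passed in each of 18 alternative settings. Map7d3 missed the threshold in edgeR without scaling (adjusted p = 0.140) and without heterozygous library 1 (0.0732), heterozygous library 2 (0.137), homozygous library 1 (0.0859) or homozygous library 3 (0.0973). Gm26561 missed it without heterozygous library 2 (0.131) or homozygous library 1 (0.0958), 2 (0.0951) or 3 (0.0616), or with gene length trends removed (0.143), and its sign turned with both strands summed (log2 fold change 0.07).

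Genes for acrosome formation, the Golgi and the piRNA machinery were fixed by name before the data were examined, because the series title names sperm acrosome overgrowth. Golga2, which encodes the Golgi matrix protein GM130, stood at 56.6 ± 6.08 CPM in wild type, 57.7 ± 5.56 in heterozygotes and 83.7 ± 9.33 in homozygotes (SD, n = 3 each). Against heterozygotes its log2 fold change was 0.53 (SE 0.11), which missed the threshold over all features (edgeR adjusted p = 0.644, DESeq2 adjusted p = 0.0258). Against wild type it rose by 0.56 (SE 0.11, edgeR adjusted p = 0.00706), a call that was lost with an elongating spermatid covariate (log2 fold change 0.42, 0.0910). The acrosome genes Gopc, Dpy19l2, Spaca1, Spata16, Zpbp, Pick1 and Acr had log2 fold changes from -0.03 (Zpbp) to 0.11 (Acr) between homozygotes and heterozygotes, and none passed in edgeR. The piRNA genes Piwil1, Piwil2, Mov10l1, Mybl1 and Tdrd1 ranged from -0.03 (Piwil1) to 0.08 (Tdrd1), also without a call. In the comparison of homozygotes with heterozygotes, 5 of 23 gene lists passed the camera test with a preset correlation of 0.01, each with small shifts. They were the interferon response (20 genes, median log2 fold change 0.11, adjusted p = 0.0279), Golgi matrix and golgin (37, 0.04), pachytene and secondary spermatocytes (25, 0.07), unfolded protein and heat shock (21, 0.09) and Leydig cell (19, -0.15), the last 4 at adjusted p = 0.0385. No member passed over all features in edgeR, and adjusted over the list alone 1 did, Golga2. With an estimated correlation 0 lists passed (adjusted p = 0.763 for each of these 5), and with fry 0 passed (0.822). Without scaling the medians were 0.06 for interferon response, -0.02 for Golgi, 0.01 for pachytene and secondary spermatocytes, 0.03 for unfolded protein and -0.21 for Leydig cell. The number of passing lists was 3 without heterozygous library 1, 2 without heterozygous library 2, 8 without heterozygous library 3 and 2 without homozygous library 1. None of these 5 lists passed in all 9 fits with 1 library left out: Golgi passed in 5, unfolded protein and heat shock in 3, and the others in 6.

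Homozygotes were compared with wild type, which shows differences that cannot be assigned to the full loss alone. Wild type also stood apart from heterozygotes (4977 calls, given below), and only 6 features passed between homozygotes and heterozygotes. By adjusted p under the naming rule, the first genes higher, apart from Gm9 (log2 fold change 3.06) and Tmem184c (2.19), were 4930568E12Rik (1.32, SE 0.10), Sfi1, a centrosomal gene (1.56, SE 0.14), Map7d3 (from 13.4 to 35.2 CPM), the metalloprotease gene Adamts9 (1.41), the ribosomal pseudogene Rpl15-ps2 (1.67), 4930486L24Rik (2.76), Scoc (1.13) and the heparan sulfate sulfotransferase gene Hs6st2 (1.04). The first lower, apart from the precursors, were 4933431M02Rik (-6.29, SE 0.17), the kallikrein genes Klk1b8 (-5.78) and Klk1b26 (-4.61), Lcn2, which encodes lipocalin 2 (-3.76), 1700029M03Rik (-3.14), the axonemal dynein gene Dnah11 (-3.20), AI987944 (-2.25) and the prostaglandin D synthase gene Ptgds (-2.84). The rule takes at most 3 placeholder symbols per direction, and some called genes fell further, such as 1700021J08Rik (-7.49). The edgeR adjusted p of these genes ranged from 7.03e-10 (4933431M02Rik) to 1.7e-04 (Hs6st2), each with homozygous and wild-type libraries that did not overlap. For example, Lcn2 fell from 184 ± 37.6 to 13.6 ± 2.03 CPM and Ptgds from 46.1 ± 1.98 to 6.43 ± 1.49 (SD, n = 3). Kallikreins and ribosomal pseudogenes have near-identical relatives, so their reads may be split among copies. Of 20782 features, 2012 were higher and 2307 lower, and the groups did not overlap for 42.6% of features, against 10% by chance. Without scaling beyond library size the split was 2225 higher and 1688 lower. The count of 4319 became 2760 without wild-type library 2, 2814 without wild-type library 3, 1899 without homozygous library 2 and 1805 without homozygous library 3, and 1932 with the elongating spermatid covariate.

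The germ cell lists differed in direction between homozygotes and wild type. Between homozygotes and heterozygotes the median was 0.05 for early meiotic prophase, 0.06 for elongating spermatids and 0.05 for flagellum and axoneme. The differences from wild type were thus mostly shared by heterozygotes. Genes of early meiotic prophase rose: 13 of 26 were higher, none lower, and adjusted over the list alone 16 were higher and 1 lower (median log2 fold change 0.34, camera adjusted p = 1.79e-05; adjusted p = 0.399 with an estimated correlation). Examples are Meiob, needed for recombination (0.76, edgeR adjusted p = 0.00129), the synaptonemal complex genes Sycp3 (0.81) and Sycp2 (0.62), and Meioc (0.56). Genes of elongating spermatids fell: 8 of 30 were lower and adjusted over the list alone 15 were (median -0.53, camera adjusted p = 6e-05; adjusted p = 0.755 with an estimated correlation). Examples are the kinase gene Tssk6 (-1.37), Oaz3 (-1.03), Prm3 (-0.89) and Dbil5 (-0.88), of which the last 3 missed the threshold with the covariate taken from this list (-0.28, -0.46 and -0.34; adjusted p = 0.211, 0.0551 and 0.0916). Sperm flagellum and axoneme genes fell in the camera test: 7 of 33 were lower and 1 higher, and adjusted over the list alone 14 and 2 (median -0.21, adjusted p = 0.0366; adjusted p = 0.755 with an estimated correlation). The 1 that was higher was the cilia gene Ccdc39 (0.46) and an example of those lower is the dynein gene Dnah17 (-0.46), and both calls were lost without homozygous library 3 (adjusted p = 0.0501 and 0.0602). The flagellum list itself missed the threshold without wild-type library 1 (0.0745), heterozygous library 3 (0.0531) or homozygous library 2 (0.0897). The lists of round spermatids (10 of 28 lower, 1 higher; 11 and 1 adjusted over the list alone), pachytene and secondary spermatocytes (4 of 25 lower, 2 higher; 4 and 2 adjusted over the list alone) and spermatogonia (3 of 23 lower, 3 higher; 3 and 4 adjusted over the list alone) did not pass camera, at adjusted p = 0.0832, 0.391 and 0.783. Neither did manchette and head shaping (3 of 28 lower; 3 adjusted over the list alone; adjusted p = 0.283), acrosome formation and contents (7 of 40 lower, 2 higher; the same counts adjusted over the list alone; 0.283), Golgi matrix and golgin (8 of 37 higher, 2 lower; 9 and 6 adjusted over the list alone; 0.144) or the piRNA pathway (8 of 31 higher, 1 lower; the same counts adjusted over the list alone; 0.225). Within these lists, the acrosomal protease gene Prss21 fell by 0.55 and the Golgi transport gene Bet1 rose by 0.55. Mybl1 and Tdrd1 stood at 0.33 and 0.28 (edgeR adjusted p = 0.0399 each) near the threshold, and their calls were lost in 7 and 8 of 18 settings. Mybl1 missed it without wild-type library 1 (0.0513), 2 (0.136) or 3 (0.0820) or homozygous library 1 (0.0511), 2 (0.151) or 3 (0.0947). Tdrd1 missed it without wild-type library 2 (0.124) or 3 (0.148) or homozygous library 1 (0.0663), 2 (0.123) or 3 (0.126).

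**Figure D2:**
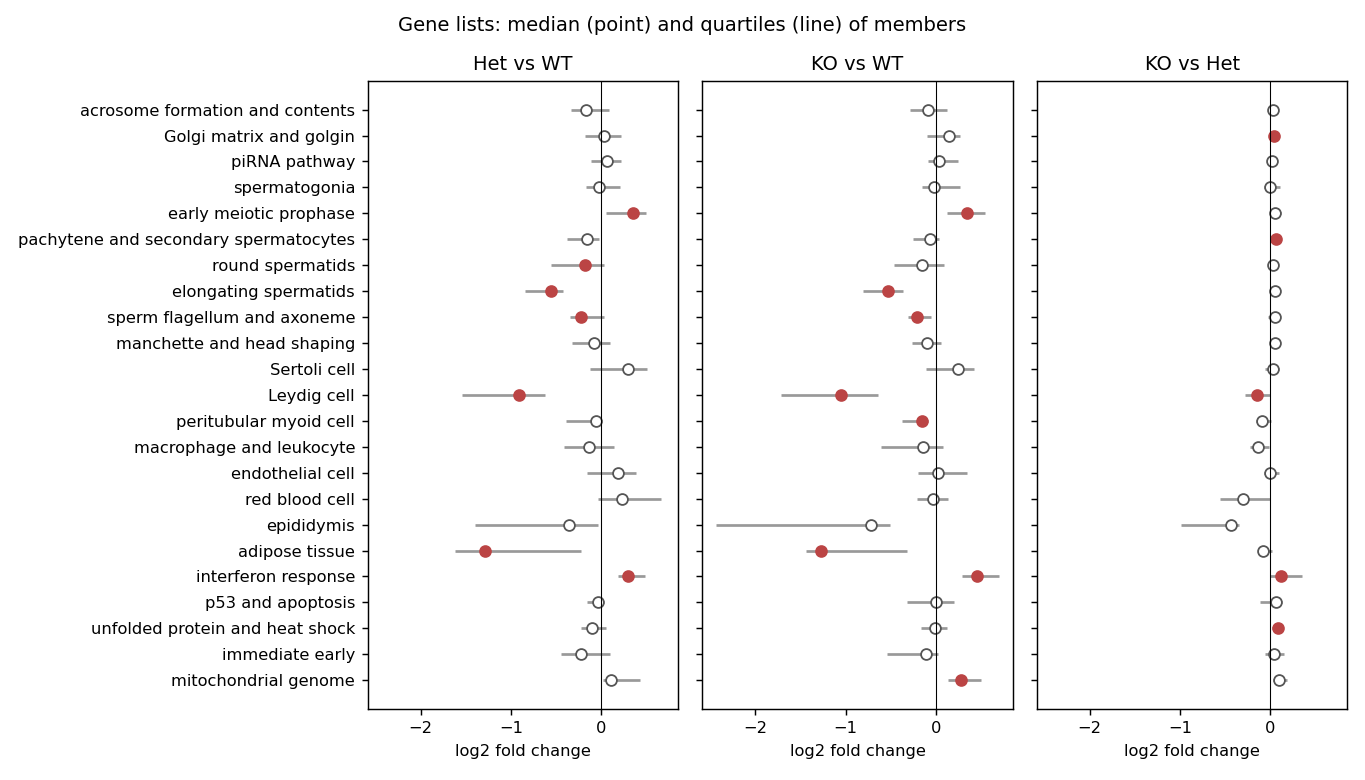
Median log2 fold change (point) and quartiles (line) of the members of 23 gene lists in the comparisons of heterozygotes with wild type, homozygotes with wild type and homozygotes with heterozygotes. Filled points passed the camera test at a preset correlation of 0.01; the Leydig cell list lies at -0.91, -1.04 and -0.15, and 0 lists passed with an estimated correlation.

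Among somatic markers, the Leydig cell genes lay below wild type in both other groups (median -0.91 in heterozygotes and -1.04 in homozygotes). Between homozygotes and heterozygotes their median was -0.15. Leydig cells make testosterone, and 15 of 19 of their genes were lower in homozygotes than in wild type (15 adjusted over the list alone; median log2 fold change -1.04, camera adjusted p = 1.42e-10; adjusted p = 0.142 with an estimated correlation). Hsd17b3, the enzyme of the last step to testosterone, fell by 1.70 on the log2 scale, from 25.5 ± 2.75 to 7.83 ± 0.06 CPM (SD, n = 3), Fabp3 by 1.84 and Sult1e1 by 2.89. Peritubular myoid genes fell in camera with 3 of 13 lower (3 adjusted over the list alone; median -0.16, adjusted p = 0.0366; adjusted p = 0.755 with an estimated correlation), among them Des (-0.69; adjusted p = 0.0507 without homozygous library 3). This list missed the threshold without wild-type library 1 (0.0595) or 3 (0.0623) or homozygous library 1 (0.139). Adipose tissue genes, a check for attached fat, were lower in 4 of 9 (5 adjusted over the list alone; median -1.27, adjusted p = 0.0366; adjusted p = 0.313 with an estimated correlation), such as Cfd (-2.89), all below 3 CPM, and the list missed the threshold without wild-type library 2 (0.0630), heterozygous library 3 (0.0807) or homozygous library 1 (0.0842). Interferon response genes rose in 5 of 20 (5 adjusted over the list alone; median 0.45, adjusted p = 7.52e-05; adjusted p = 0.142 with an estimated correlation), with the RNA sensor gene Ifih1 at 0.70 (adjusted p = 0.0518 without homozygous library 2). Mitochondrial genome transcripts were higher in 4 of 14 and lower in 1 (5 and 1 adjusted over the list alone; median 0.28, adjusted p = 0.0137; adjusted p = 0.755 with an estimated correlation), among them mt-Cytb (0.61), and the list missed the threshold without wild-type library 3 (0.107). The Sertoli cell (6 of 23 higher, 1 lower; 8 and 2 adjusted over the list alone), macrophage and leukocyte (5 of 19 lower, 1 higher; the same counts adjusted over the list alone) and endothelial cell (0 of 15 in edgeR over all features, and 0 adjusted over the list alone) lists did not pass camera, at adjusted p = 0.0543, 0.0832 and 0.709. Neither did red blood cell (1 of 6 lower; 1 adjusted over the list alone; 0.783), epididymis (0 of 6 in edgeR; 0 adjusted over the list alone; 0.585), p53 and apoptosis (3 of 19 higher, 1 lower; the same counts adjusted over the list alone; 0.888), unfolded protein and heat shock (1 of 21 higher, 3 lower; 2 and 4 adjusted over the list alone; 0.783) or immediate early (1 of 14 lower; 1 adjusted over the list alone; 0.669). The epididymal gene Crisp1 varied widely within wild type, at 11.1 ± 17.1 CPM.

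Heterozygotes were compared with wild type, where the cause of the differences stays open, because wild type stood apart from both other groups. Most genes named here were also named in the homozygotes. By adjusted p under the naming rule, the first 10 genes higher were 4930568E12Rik (log2 fold change 1.34), Sfi1 (1.83), Hs6st2 (1.12), Adamts9 (1.38), 4930486L24Rik (2.65), Gm47051 (1.12), Rpl15-ps2 (1.54), Gprin3 (1.66), Scoc (1.02) and the collagen gene Col28a1 (1.24). The first 10 lower were 4933431M02Rik (-6.73), Klk1b8 (-5.63), Lcn2 (-3.33), 1700029M03Rik (-3.23), AI987944 (-2.48), Klk1b26 (-4.24), Ubxn10 (-1.41), Dnah11 (-2.74), Rpl34-ps1 (-1.96) and Ptgds (-2.41). Their edgeR adjusted p ranged from 7.68e-10 (4933431M02Rik) to 3.4e-04 (Col28a1). Of 20782 features, 2302 were higher and 2675 lower (42.1% without overlap between the groups, 10% by chance). Without scaling beyond library size 3175 were higher and 1575 lower, and the median of all features moved from -0.00 to 0.10. The count of 4977 became 2901 without wild-type library 1, 2432 without heterozygous library 3 and 1041 with the elongating spermatid covariate. In this comparison 7 lists passed camera: early meiotic prophase (13 of 26 higher, 2 lower; 15 and 2 adjusted over the list alone; median 0.35), round spermatids (10 of 28 lower, 1 higher; 11 and 2 adjusted over the list alone; -0.19), elongating spermatids (13 of 30 lower; 21 adjusted over the list alone; -0.56), sperm flagellum and axoneme (12 of 33 lower, 2 higher; the same counts adjusted over the list alone; -0.22), Leydig cell (15 of 19 lower; 15 adjusted over the list alone; -0.91), adipose tissue (5 of 9 lower; 5 adjusted over the list alone; -1.29) and interferon response (2 of 20 higher; 0 adjusted over the list alone in edgeR; 0.29). With an estimated correlation 0 of 23 lists passed (adjusted p = 0.676 for early meiotic prophase, 0.694 for round spermatids, elongating spermatids and flagellum, and 0.368 for Leydig cell, adipose tissue and interferon response). Without heterozygous library 1, 4 lists passed. Round spermatids missed the threshold without wild-type library 2 (0.111) or 3 (0.176) or heterozygous library 1 (0.101), and adipose tissue without wild-type library 2 (0.0861) or heterozygous library 1 (0.0510) or 3 (0.104). Flagellum missed it without heterozygous library 1 (0.104) and interferon response without heterozygous library 2 (0.0746).

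**Figure D3:**
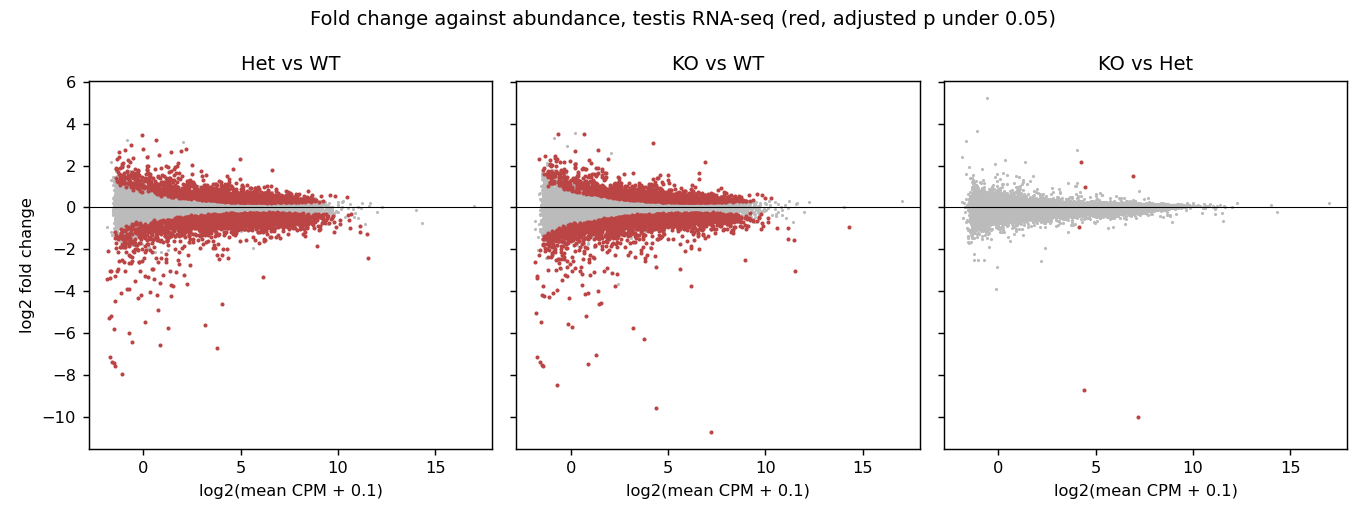
Log2 fold change against log2 of the mean CPM plus 0.1 for each tested feature in 3 comparisons of testis RNA-seq. Red points passed at an adjusted p under 0.05: 4977 between heterozygotes and wild type, 4319 between homozygotes and wild type, and 6 between homozygotes and heterozygotes.

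Homozygotes were also set against the mean of wild type and heterozygotes, which the labels call controls. Beside Gm9 (log2 fold change 2.61), Tmem184c (1.85) and Map7d3 (1.19), the genes higher by the naming rule were Rassf9 (1.04, SE 0.12, edgeR adjusted p = 0.00152), Gm649 (1.55), 1 gene without a symbol (ENSMUSG00000085550.1, 1.26) and Nlrp5, an oocyte maternal-effect gene (1.27, adjusted p = 0.0280). Beside the precursors, those lower were Hsd17b3 (-1.06, SE 0.11, adjusted p = 6.16e-04), Sardh (-1.28), Gm1821 (-1.03), Tmem189 (-1.82), the G protein gene Gnal (-1.30) and the cytokine receptor gene Il17rb (-1.95). Against heterozygotes alone, none of these 6 and none of Rassf9, Gm649, ENSMUSG00000085550.1 and Nlrp5 passed in edgeR. In Gm649 and in 4 of those lower, heterozygotes differed more from wild type than homozygotes did from heterozygotes: Hsd17b3 stood at -0.41 against heterozygotes (adjusted p = 1.00) while heterozygotes lay 1.29 below wild type, and Sardh at -0.41 and 1.74. Rassf9 stood at 27.5 ± 3.58 CPM in homozygotes (SD, n = 3) and 13.7 ± 3.37 in controls (SD, n = 6). Golga2 rose by 0.55 (adjusted p = 0.0241), a call lost without wild-type library 2 (0.0675) or 3 (0.0672), heterozygous library 2 (0.0634) or homozygous library 1 (0.102), 2 (0.104) or 3 (0.0614), and with both strands summed (0.1001). Gm649 missed the threshold without homozygous library 1 (0.0596) or 2 (0.0504), ENSMUSG00000085550.1 without homozygous library 1 (0.0650) or 3 (0.126) and with both strands summed (log2 fold change 0.22, 0.384), and Il17rb without homozygous library 3 (0.0517). Nlrp5 missed it without wild-type library 1 (0.0534) or 2 (0.0675), heterozygous library 2 (0.0536) or homozygous library 2 (0.151) or 3 (0.163), and without scaling (0.0572). Tmem189, which missed it with both strands summed (log2 fold change -0.50, 0.168), overlaps other genes of its strand. Of 20782 features, 53 were higher and 82 lower, and homozygous libraries lay outside all controls for 2.53% of features, against 2.38% by chance. These calls are against the mean of the 2 control groups and need not hold against each. For example, 4933431M02Rik was called lower (-2.92, edgeR adjusted p = 1.66e-05) at 0.507 CPM in homozygotes, 0.379 in heterozygotes and 39.9 in wild type. The count of 135 became 310, 63 and 298 without heterozygous library 1, 2 or 3, 52, 45 and 41 without homozygous library 1, 2 or 3, and 55 and 80 without wild-type library 2 or 3. It was 619 with DESeq2 and 584 with no filter. Camera passed 8 lists, led by Leydig cell (5 of 19 lower; 15 adjusted over the list alone; median -0.58; adjusted p = 0.0992 with an estimated correlation). The others were interferon response (median 0.29; adjusted p = 0.0992 with an estimated correlation), early meiotic prophase (0.19), mitochondrial genome (0.24), elongating spermatids (-0.23), peritubular myoid cell (-0.12), macrophage and leukocyte (-0.19) and Golgi matrix and golgin (0.07). The shift of elongating spermatids came from wild type alone, since their median was 0.06 against heterozygotes. Most other lists also moved less against heterozygotes than against wild type: Leydig cell -0.15 and -1.04, early meiotic prophase 0.05 and 0.34, interferon response 0.11 and 0.45. Mitochondrial genome stood at 0.10 and 0.28 and Golgi at 0.04 and 0.14. Peritubular myoid cell (-0.10 and -0.16) and macrophage and leukocyte (-0.13 and -0.14) were closer. Adjusted over the list alone, 2, 7, 4, 0, 0, 2 and 2 genes of the lists after Leydig cell passed in edgeR, and 0 of 23 lists passed with an estimated correlation. The number of passing lists was 5 without heterozygous library 2 and 4 without homozygous library 1. Elongating spermatids passed in 6 of 9 fits with 1 library left out, macrophage and leukocyte in 4, Golgi in 3 and peritubular myoid cell in 8.

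The comparisons share libraries, and their overlap was counted beside chance. Homozygotes against wild type and against heterozygotes shared 5 calls (3 higher and 2 lower): Gm9, Tmem184c, Map7d3 and the precursors. Independent lists would share 0.290 and 0.333. In 20 simulations of unchanged groups with the same shared libraries the mean was 0. Hardly any feature passes in unchanged groups, so this 0 cannot measure what sharing libraries adds. At an unadjusted edgeR p under 0.05 the 2 comparisons shared 224 features, against 218.8 in the simulations, so no excess was seen there. The fold changes correlated across genes, which are not independent, at r = 0.30 (simulated 0.50), with a covariance of 0.0429 (simulated 0.0312). Homozygotes and heterozygotes, each against wild type, shared 3475 calls (1564 higher, 1911 lower). Independent lists would share 222.9 and 297, and the simulations gave 0, with the same limit. At an unadjusted edgeR p under 0.05 they shared 6027, against 217.1 in the simulations. Their covariance was 0.244 (simulated 0.032). The wild-type group has too few libraries to be split, and part of the excess may come from the shared wild-type libraries.

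Genes within 1 Mb of the precursors were examined because they lie near a deletion. Of 18 tested, 2 were higher and 3 lower in homozygotes than in wild type, and 1 higher and 3 lower in heterozygotes than in wild type. Over all features, 20.8% passed between homozygotes and wild type and 23.9% between heterozygotes and wild type. The number of calls thus does not set the neighbours apart from other genes. Between homozygotes and heterozygotes 0 neighbours passed in edgeR (3 at an unadjusted p under 0.05). Gnal, which encodes a G protein alpha subunit, starts 3.96 kb downstream of the plus-strand precursor, on the same strand. It fell from 7.94 ± 0.84 CPM in wild type to 4.82 ± 0.29 in heterozygotes and 2.51 ± 0.76 in homozygotes (SD, n = 3 each). Counts cover whole gene bodies, introns included, so the Gnal count need not come from its own transcripts alone. Its log2 fold change was -1.66 against wild type (SE 0.20, edgeR adjusted p = 5.38e-04) and -0.94 against heterozygotes (adjusted p = 0.644). In heterozygotes against wild type it was -0.72 (adjusted p = 0.0196), a call lost without wild-type library 2 (0.0577) or 3 (0.0565), without scaling (0.0556) or with the covariate (log2 fold change -0.66, 0.178). Impa2, which encodes an inositol monophosphatase, fell from 2.73 ± 0.33 in wild type to 1.10 ± 0.09 in homozygotes (log2 fold change -1.31, adjusted p = 0.00434). The Impa2 call was lost with both strands summed (log2 fold change -0.37, 0.0722) or with the covariate (log2 fold change -0.89, 0.0660). Tubb6, a beta-tubulin gene, stood at 22.1 ± 0.23, 8.47 ± 0.85 and 8.28 ± 1.00 in wild type, heterozygotes and homozygotes. Cidea, a lipid droplet gene, stood at -0.59 in heterozygotes against wild type (adjusted p = 0.0273). The Cidea call was lost without wild-type library 1 (0.0889) or 2 (0.0687), heterozygous library 2 (0.0522) or 3 (0.0918), or without scaling (0.0666). It was also lost with the covariate (0.0765), though the log2 fold change there was larger, at -0.82. Ptpn2 rose by 0.43 against wild type (adjusted p = 0.00626; log2 fold change 0.38 and 0.0655 with the covariate). Cep192 stood at 0.30 (adjusted p = 0.0415), a call lost in 9 of 18 settings, among them without wild-type library 1 (0.0524), 2 (0.105) or 3 (0.122) or homozygous library 1 (0.0559), 2 (0.137) or 3 (0.116). Over all 459 tested features of chromosome 18, the camera p was 0.389 against wild type and 0.194 against heterozygotes.

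Small RNA reads were compared to ask which annotated genes gained or lost protected small RNAs when the last copy was lost. Unc119b, a chromosome 5 gene for a lipid-binding trafficking protein, lost most of its sense small RNA reads. They fell from 324 ± 44.1 CPM in heterozygotes to 55.3 ± 11.9 in homozygotes (SD, n = 3 each), a 5.84-fold decrease (log2 fold change -2.55, SE 0.22, edgeR adjusted p = 0.00538). Its raw reads were 491, 369 and 374 against 100, 63 and 46. Its RNA-seq level did not pass (log2 fold change 0.20, SE 0.11, edgeR adjusted p = 1.00). Kdelr2, a gene for a Golgi to endoplasmic reticulum retrieval receptor, had a log2 fold change of -1.78 (adjusted p = 0.184), and the transporter gene Slc43a2 of -0.99 (0.188). Golga2 small RNA stood at -0.45 (adjusted p = 0.557), while Tmem184c, Gm9 and Map7d3 had at most 4 reads per library. Kdelr2, Slc43a2, Tmem184c, Gm9 and Map7d3 were chosen here after their values were seen. So was the small RNA value of Golga2, a gene fixed by name for RNA-seq. Of 3581 genes tested, 0 were higher and 1 lower, with 312 at an unadjusted p under 0.05 and 1 call by DESeq2. Unc119b missed the threshold without homozygous library 2 (0.130) or 3 (0.0619), and then 0 genes passed in edgeR. Without heterozygous library 1, 617 genes passed, and without heterozygous libraries 2 and 3, 67 did. Those 2 libraries held less mitochondrial tRNA (0.106 and 0.160% of reads, against 0.806 to 1.17% in the other 4) and less snoRNA and snRNA (0.790 and 0.932%, against 2.91 to 5.53%). The precursors themselves are not features of these counts, and their small RNAs were not analysed here.

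**Figure D4:**
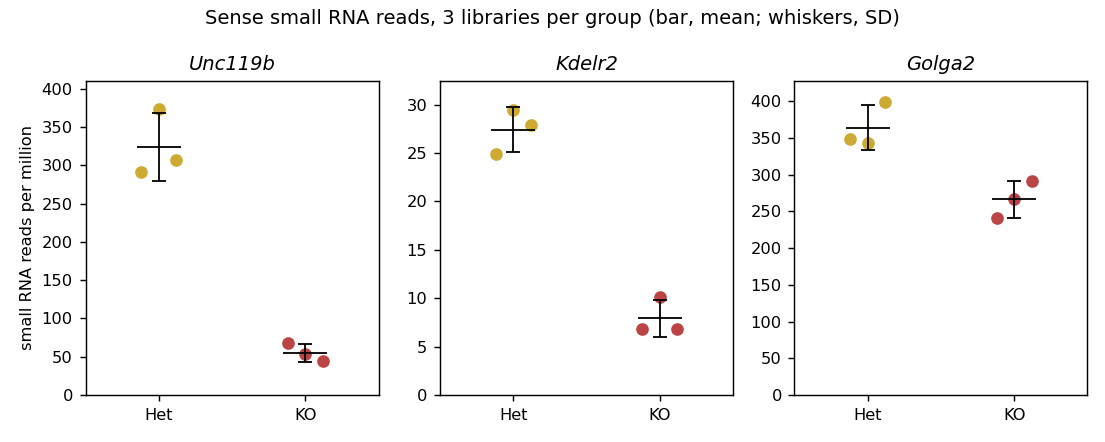
Sense small RNA reads in CPM (linear axes from 0) of Unc119b, Kdelr2 and Golga2 in 3 heterozygous (Het) and 3 homozygous (KO) libraries. Points are libraries, bars are means and whiskers are SDs; Unc119b lies at 324 in heterozygotes and 55.3 in homozygotes, while Kdelr2 and Golga2 did not pass the test.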

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

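The test of reads from a near-identical copy of the locus and the tests on heterozygous small RNA libraries 2 and 3 were chosen after the results were seen, and so was the repeat of the neighbour test without overlapping genes.

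RNA-seq counts of the opposite strand lie outside the main measurement, and features changed there too. Of 12303 tested with edgeR, 1193 passed between homozygotes and wild type and 30 between homozygotes and both controls. Between homozygotes and heterozygotes 0 passed, with 472 at an unadjusted p under 0.05.

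Wild-type libraries stood apart from both other groups: on the first principal component (43.6% of the variance) they lay at -57.2, -41.2 and -40.4 and the other 6 at 13.8 to 31.3. Log2 fold changes rose with gene body length, with a Spearman rho of 0.27 between heterozygotes and wild type and 0.20 between homozygotes and wild type. With each library's trend removed, 4300 calls between heterozygotes and wild type were made, 3665 of them among the 4977 made before. This argues against a length trend, as from unspliced RNA, as the whole cause. The medians of 5 somatic lists spread over 1.21 log2 units (-0.91 for Leydig cell to 0.30 for Sertoli cell). That spread argues against a shift of all somatic cells together as the whole cause. A changed share of 1 cell type, such as Leydig cells, would also give a spread, so this test cannot decide on it. Another strain or line background in the wild-type animals may contribute: of 82 genes at least 4-fold different in both other groups, 13.4% had another such gene within 500 kb, against a 95th percentile of 10.98% in 1000 random sets (highest 19.5%). Without overlapping genes the share was 10.98%, at that percentile. With the elongating spermatid covariate 1041 calls between heterozygotes and wild type were made. The list behind this covariate itself separates wild type from heterozygotes (median -0.56) and homozygotes (-0.53). Calls can therefore be lost with it whatever the cause, and the drop cannot decide on germ cell stage. Background, germ cell stage and an effect of the deletion in both genotypes stay open.

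Heterozygous small RNA libraries 2 and 3 held less mitochondrial tRNA, snoRNA and snRNA than the other 4. A stronger removal of RNAs without 2′-O-methylation would also lower miRNA, which is not methylated in mammals. In heterozygous library 3 miRNA made up 3.49% of reads, above the median of 3.30% in the other 4 (library 2 held 3.28%, just below it), which argues against that removal as the whole cause. No biological explanation was tested, since both libraries carry the label of heterozygous library 1.

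Sense small RNA reads of Unc119b and, without passing, of other genes were lower in homozygotes. For Unc119b a lower RNA level is argued against, since its RNA-seq log2 fold change was 0.20 (SE 0.11), with introns counted too. The 32 genes whose small RNA fell at an unadjusted p under 0.01 (median -0.98) include Unc119b. They had a median RNA-seq log2 fold change of 0.0566, above the 0.0329 of random sets. Only Unc119b passed with adjustment, so the others may have fallen by chance, and the set cannot decide for them. Reads of the locus itself could have been assigned to a similar copy. Unc119b matches the plus-strand transcript in antisense, so only reads of the other strand there could count as its sense reads. Opposite strand counts over the plus-strand precursor were 0.0854% of both strands in heterozygotes (2 against 2340), but reads were counted in only 15.3% of it, outside the stretch that matches Unc119b, and in long RNA. So opposite strand reads of the locus assigned to a similar copy stay open, as does an effect of the genotype.

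Other splits of the libraries were compared with the real ones. Between homozygotes and wild type 1 of 10 splits gave as many features (4319, highest other 0), between heterozygotes and wild type 1 of 10 (4977, highest other 0), between homozygotes and heterozygotes 3 of 10 (6, highest other 18), and in small RNA 2 of 10 (1, highest other 1). With 10 splits no share under 0.05 can be reached. For homozygotes against both controls 2 of 100 drawn splits gave as many (135, highest other 175), but most of these splits could not match it. Splits with 1 or 2 wild-type libraries in the set of 3 gave at most 7 and 6, since wild type stands apart. Of the 24 splits with 0 there, 2 gave as many, the real one included, so chance was not excluded for this count.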

How the results depend on the processing

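The correction of length trends, the small RNA fit without heterozygous libraries 2 and 3 and the alternatives for the opposite strand were chosen after the results were seen. Of 316 values of the comparisons under alternatives, 249 stayed within 1.5 times, and of 8404 values of named genes 7866 stayed on the same side of the threshold, 421 lost and 113 gained a call, and 4 turned sign with a call in either fit. Counting genes without a call, 84 values in 50 of 476 results had another sign. Gm9, Tmem184c and the precursors kept theirs in each setting run. The causes of the changes below were not tested.

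With both strands summed, Uso1 turned to -0.0455 against wild type in homozygotes and -0.0327 in heterozygotes, and Gm26561 to 0.0721 between homozygotes and heterozygotes. With the elongating spermatid covariate, Actg2 turned to 0.0237 between heterozygotes and wild type. The 2-fold limit, which by construction passes fewer features, gave 745 (homozygotes against wild type), 684 (heterozygotes against wild type) and 51 (both controls), and the covariate 1932 and 1041 for the first pair. No filter gave 13 (homozygotes against heterozygotes) and 584 (both controls), and DESeq2 17 and 619. Calls shared by the homozygote comparisons were 224 at an unadjusted p (218.8 in simulations of unchanged groups) and 13 with DESeq2. Camera with an estimated correlation passed 0 lists in every comparison. Against wild type, fry passed 4 in homozygotes and the same 4 in heterozygotes: early meiotic prophase, Leydig cell, adipose tissue and interferon response. It passed 0 between homozygotes and heterozygotes and 3 for both controls, the same lists without adipose tissue. On the opposite strand no filter gave 35 (homozygotes against heterozygotes) and 267 (both controls).

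With 1 library left out, calls ranged from 1805 to 4737 (homozygotes against wild type), 4 to 18 (homozygotes against heterozygotes), 2432 to 4720 (heterozygotes against wild type), 41 to 310 (both controls) and 4 to 7 (shared calls). Passing lists ranged from 6 to 10, 2 to 8, 4 to 9 and 4 to 9 in the same 4 comparisons, and opposite strand calls from 338 to 1511, 0 to 4, 439 to 1458 and 9 to 95.

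Small RNA calls numbered 43 with no filter, 67 without heterozygous libraries 2 and 3 and 0 to 617 with 1 library left out. With the replicate block 0 genes passed (Unc119b adjusted p = 0.0923, range over settings 2.53e-19 to 0.130). The numbers share no deviations (r = -0.155, 0.0028 and -0.0885), so they do not pair the libraries. The gaps for joining locus features were not run, since no such features were counted.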

Other observations

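The values of genes with antisense matches in the small RNA data were looked up after the results were seen.

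A hypothesis was tested that genes higher in homozygotes than in heterozygotes are normally held down by small RNAs of the locus that are antisense to them. Annotated transcripts of the locus matched 23 genes in antisense outside repeat-like stretches, among which Gm9, Tmem184c, Map7d3 and Golga2 were not found. One of the 23 was 4930568E12Rik (109 nt at 90.8% identity), named above as higher than wild type in both other groups. The matching genes were not tested as a set against wild type. The 14 of them tested in RNA-seq had a median log2 fold change of -0.0401 between homozygotes and heterozygotes, against 0.0109 in 1000 random sets (95th percentile 0.0720), and 0 passed in edgeR. The annotated transcripts cover 100% of the plus-strand precursor and 5.6% of the minus-strand one, so loss of antisense small RNAs from the minus strand stays untested. Alignments under 100 nt were not kept, and of 909 genes with a longer one, most matched only repeat-like stretches and were left out. The values therefore cover only long matches outside repeats, and the hypothesis stays open for both strands.

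Unc119b aligned in antisense to a plus-strand transcript over 1377 nt at 95.3% identity. Of 3 matching genes tested in small RNA, 1 passed, Unc119b, while Ankrd17 (log2 fold change 0.11) and Dcbld2 (-0.25) did not. The matches of Ankrd17 and Dcbld2 were far shorter, 101 nt at 83.2% identity each, so the 3 genes are not like cases.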
